A study of Caenorhabditis elegans with 9 samples.

How the data were processed

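The samples were 9 poly(A)-selected messenger RNA libraries from synchronized young adult C. elegans, 3 each of the genotypes labelled WT, UNC5 and PATR1. As deposited, the values are raw read counts per gene, made by the authors with quality checks in FastQC 0.11.9, adapter trimming in cutadapt 3.5 and alignment and counting in STAR 2.7.11b to WBcel235, with no normalization or filtering. The design text names the WS288 release, and the authors' own statistics and code were not used here.

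Each file gives counts for 46926 genes without strand and for each strand. By a rule set before the data were examined (the total of the strand at least 5 times that of the opposite strand), the reverse-strand counts were used, whose totals were 41.9 to 57.1 times those of the opposite strand. Gene positions came from the Ensembl release 115 annotation of WBcel235, which held 46918 of the identifiers, and 8 were not in it. Total counts per library ran from 38673206 to 60642199, and 21206 to 22423 genes per library had counts. Reads without a place in the genome, with several places, or in no gene were read from the head of each file and kept out of the fits.

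Genes were kept by filterByExpr of edgeR 4.0.16, which left 17512. Libraries were scaled with TMM factors, which lay between 0.954 and 1.04, and all 9 libraries were fitted together in a robust edgeR quasi-likelihood model in R 4.3.3. The model compared UNC5 with WT, PATR1 with WT and PATR1 with UNC5, with p-values adjusted by the Benjamini-Hochberg method over the genes of each comparison. A gene was called at an adjusted p below 0.05 and an absolute log2 fold change above 1, and in gene lists "rose", "fell", "higher" and "lower" mean an adjusted p below 0.05. The common biological coefficient of variation was 3.14%. Pairs of libraries of 1 group differed by a median chi-square 1.49 to 2.35 times that of counting error alone.

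The 30 gene lists, the tests and the rule for naming genes were fixed before the data were examined, and 14 list members matched no gene. The mitochondrially encoded list was matched as the 12 protein-coding genes of the mitochondrial chromosome. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, which compares a list with all other genes. Camera with an estimated correlation and fry were alternatives. fry tests whether the genes of a list move one way on balance, not whether they move more than other genes. The named genes were unc-5 always; the 8 largest rises and 8 largest falls against WT, and 5 and 5 between the mutant groups, among called genes with a mean of at least 5 CPM, a symbol that is not a clone name and no overlap of the groups' libraries; up to 4 members of each list with the smallest adjusted p below 0.05; and up to 5 genes per direction called in both mutant groups with the largest smaller change. The limits on CPM and symbol were applied to this last part too, although the rule as fixed does not state them for it. The text prints some of the 267 genes that this rule gives. Fold changes in x-fold form are ratios of pooled counts over scaled library sizes. Where a group had 0 counts the bound used a floor of 3 counts over the group, and where it had 1 to 3 counts the ratio is given with its 95% counting interval.

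The sharing of calls was set against 20 simulations in which all 9 libraries were drawn from the WT means. In these, both comparisons shared the simulated WT libraries. Calls per chromosome, and within 2 Mb of unc-5, were compared by Fisher's exact test. The pipeline was tested on simulated data with 17512 genes: of 50 genes changed by a factor of 1.2, 27 to 31 were recovered at an adjusted p below 0.05, of 50 changed by a factor of 3, 49 or 50, and 13 to 21 unchanged genes passed.

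The alternatives tried were relative log expression factors, library sizes alone, no low-count filter (26606 genes), a filter at 5 CPM in 3 libraries (11491 genes), the Wald test of DESeq2 1.42.0, the unstranded counts, only the 6 libraries compared, the replicate number as a block, leaving out each library, camera with an estimated correlation, fry, and the adjusted p alone for chromosomes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the plots. GC content was not analysed here.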

Results

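Messenger RNA was sequenced from whole young adult nematodes of the species Caenorhabditis elegans. The 9 libraries fall into 3 genotypes labelled WT, UNC5 and PATR1, with 3 libraries each. The design describes a wild type and a strain with an unc-5 stop-codon allele, compared to find the genes, neuronal genes among them, whose RNA level differs between the strains. unc-5 encodes a receptor for the secreted guidance cue netrin, which steers migrating axons and cells. The labels do not tie the stop allele to either mutant label and do not say what PATR1 stands for, so each mutant group was compared with WT and the mutant groups were compared with each other.

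The WT libraries held 56713370, 57583085 and 60642199 reads counted to genes, the UNC5 libraries 38673206, 40657389 and 45911861, and the PATR1 libraries 46269149, 40657619 and 55150409. Of 46926 annotated genes, 17512 had enough counts to be tested. Reads without a place in the genome made up 0.621% to 0.629% of all reads in WT, 0.667% to 0.937% in UNC5, and 6.02%, 3.43% and 2.86% in PATR1 replicates 1, 2 and 3. Levels are in CPM, the counts of a gene scaled to the size of its library. Spearman correlations of log2 CPM were 0.998 to 0.999 between libraries of a genotype and 0.945 to 0.965 between genotypes. The first principal component held 58.4% of the variance and parted WT from both mutant groups, and the second held 35.8% and parted UNC5 from PATR1. Below, a level is the mean CPM ± SD over the 3 libraries of a group, and a log2 fold change is given ± SE of the fit. The p-values measure only the spread between these libraries, which may be technical, since the labels do not say whether replicates were grown separately. A difference between the groups in culture or exact stage can therefore not be told apart from one of genotype.

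unc-5 itself (WBGene00006745, a protein-coding gene on the minus strand of chromosome IV, from 5495664 to 5528338 in WBcel235) was lower in both mutant groups than in WT. It stood at 16.7, 18.4 and 18.3 CPM in the WT libraries, at 10.1, 9.88 and 10.3 CPM in UNC5, and at 13.8, 13.8 and 12.75 CPM in PATR1, from 397 to 1155 counts per library. The UNC5 mean was 56.8% of the WT mean (log2 fold change -0.82 ± 0.058, adjusted p = 2.9e-14) and the PATR1 mean was 75.7% of it (-0.40 ± 0.054, adjusted p = 4.5e-08), with all 3 libraries of each mutant group below all 3 WT libraries. Between the mutant groups, unc-5 was higher in PATR1 (0.41 ± 0.062, adjusted p = 4.5e-07). None of the 3 differences reached 2-fold, and an exact two-sided permutation test of 3 against 3 libraries gave p = 0.1 for each, the smallest value it can give. Such separation was common, as the libraries did not overlap with WT for 77.9% of all tested genes in UNC5 and 84.0% in PATR1. In PATR1 unc-5 fell no more than the median of 277 neuronal genes (-0.53). In UNC5 the medians of the neuronal lists lay between -0.03 (ciliated sensory neurons) and 0.47 (touch receptor neurons). The gene patr-1, looked up after the values were seen because of the PATR1 label, was not lower in either mutant group, with 231 ± 5.03 CPM in WT, 300.2 ± 9.08 CPM in UNC5 and 293 ± 4.77 CPM in PATR1.

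**Figure D1:**
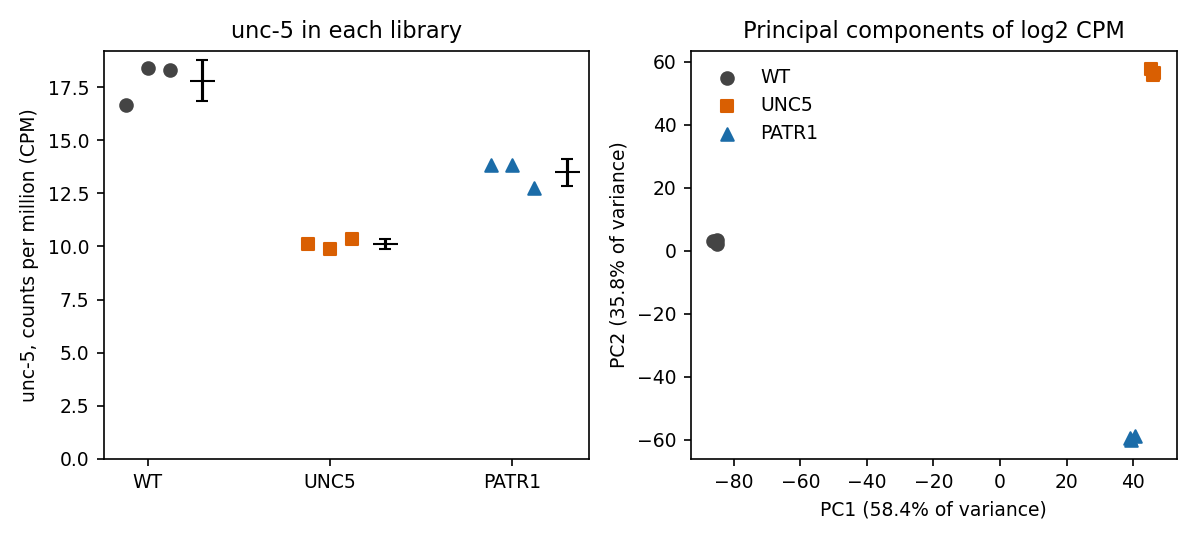
Left, the level of unc-5 in CPM in each library (points, 3 per genotype) with the group mean and SD (bar); right, the same 9 libraries on the first and second principal components of log2 CPM, with the percentage of variance on each axis. The UNC5 libraries lie between 9.88 and 10.3 CPM and the PATR1 libraries at or below 13.8 CPM, below the WT libraries at 16.7 to 18.4 CPM.

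Most sperm, yolk protein and cuticle collagen genes tested fell in UNC5 relative to WT, while most histone, neuropeptide, germline and mitochondrially encoded genes tested rose. Of the list calls behind these groups, the one for sperm genes other than major sperm proteins held with an estimated correlation (adjusted p = 0.00367). The others did not: major sperm proteins (adjusted p = 0.0874), yolk proteins and collagens (0.16 each), histones (0.115), neuropeptides (0.565), germline (0.216) and mitochondrially encoded genes (0.292). The largest changes are named here and below among called genes with at least 5 CPM on average, a symbol that is not a clone name and no overlap of the groups' libraries, and genes outside these limits changed by more in places. The largest falls were in col-102, a cuticle collagen gene, from 414 ± 11.5 to 0.115 ± 0.0995 CPM (3713.5-fold, log2 fold change -11.83 ± 0.095, adjusted p = 5.0e-35), and in cut-1, a cuticlin gene, from 683 ± 39.7 to 0.359 ± 0.219 CPM (1952.5-fold, log2 fold change -10.92 ± 0.12, adjusted p = 2.1e-18). The largest rise was in pho-10, an acid phosphatase homolog, from 0.568 ± 0.108 to 31.9 ± 1.57 CPM (56.5-fold, log2 fold change 5.81 ± 0.089, adjusted p = 3.2e-32). In total 3645 of 17512 genes passed an adjusted p below 0.05 with an absolute log2 fold change above 1, 1241 of them higher and 2404 lower. On the adjusted p alone 13455 of the 17512 passed, 8727 higher and 4728 lower. The counts of higher and lower genes in each list below are to be set against these. The libraries of the groups did not overlap for 77.9% of genes, where chance gives 10%.

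A total of 39 called genes rose more than 16-fold. Within the limits above, the other rises among the 8 largest in UNC5 were oac-53, an acyltransferase homolog (36.1-fold), the C-type lectin genes clec-190 (33.8-fold) and clec-70 (24.6-fold), the serpentine receptor gene srr-2 (25.6-fold), scl-11 (19.7-fold), the beta-tubulin gene tbb-6 (15.6-fold) and parg-2 (13.6-fold). The other large falls were again mostly in collagen genes, with col-84 1659-fold lower, col-123 1469-fold, col-164 1307-fold, col-114 1219.5-fold, col-43 1148-fold and grl-19 1146-fold lower. Some of these folds rest on UNC5 replicate 1, the highest UNC5 library for these genes. Without it the fold moved by more than 1.5 times, on the log2 scale in col-102 (from -11.83 to -12.74), cut-1 (from -10.92 to -11.51), col-84 (from -10.68 to -11.48), col-123 (from -10.49 to -11.13) and col-164 (from -10.32 to -11.18). With the unstranded counts the change was smaller, -9.38 in col-123 and -10.004 in col-84. Reads with several places in the genome are counted for no gene. Near-identical copies in the collagen, major sperm protein and histone families can lose reads in this way, so single members of those families are uncertain.

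Gene lists fixed before the data were examined were tested with camera, and for UNC5 against WT 15 of 30 lists were called, 7 higher and 8 lower. Adjusted over the list alone, the counts of a list equalled those over all genes tested unless a further count is given. Only the call of the other sperm genes held when the correlation between genes was estimated from the data. The UNC5 libraries also differed from WT in reads in no annotated gene (1.11% to 1.32% against 0.582% to 0.647%) and in reads with several places in the genome (3.57% to 3.63% against 4.69% to 4.96%).

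Of 29 major sperm protein genes, which form the sperm cytoskeleton, 28 fell and 1 did not pass, 26 of them by more than 2-fold, and 29 fell adjusted over the list alone. The most certain were msp-31, from 83.8 ± 3.17 to 21.8 ± 0.359 CPM, and msp-56, from 69.1 ± 3.65 to 13.6 ± 0.596 CPM (list median -1.68, camera adjusted p = 5.4e-18, adjusted p = 0.0874 with an estimated correlation). Among 41 other sperm genes, 37 fell, all by more than 2-fold, 2 rose and 2 did not pass (median -1.95, camera adjusted p = 1.3e-17, adjusted p = 0.00367 with an estimated correlation). The sperm phosphatase genes gsp-3 and gsp-4 fell 5.07-fold and 5.04-fold, ssq-2 fell 4.73-fold and ssq-1 4.53-fold. All 6 vitellogenin genes, which encode yolk proteins made in the intestine, fell, 2 of them by more than 2-fold: vit-1 went from 3003 ± 39.4 to 662 ± 6.95 CPM and vit-3 from 2216 ± 68.2 to 1032 ± 4.05 CPM (median -0.83, camera adjusted p = 2.9e-06, adjusted p = 0.16 with an estimated correlation). Germline and oocyte genes moved the other way, with 52 of 69 higher, 6 lower and 11 not passing (median 0.43, camera adjusted p = 2.9e-06, adjusted p = 0.216 with an estimated correlation). nos-2 rose 2.74-fold, pos-1, which encodes a maternal RNA-binding protein, 2.07-fold, and chs-1, which makes eggshell chitin, 1.91-fold. Of 33 early embryo zygotic genes, 24 rose, 25 adjusted over the list alone, 4 fell and 5 did not pass (median 1.11, camera adjusted p = 0.0338, adjusted p = 0.138 with an estimated correlation). Of these, skr-10 was 4.89-fold and skr-7 3.24-fold higher. Only 32 of 72 histone genes had enough counts to be tested, and how fully poly(A) selection captures their messages was not checked. Of these 32 genes, 26 rose and 3 fell (median 1.00, camera adjusted p = 0.0114, adjusted p = 0.115 with an estimated correlation). Of these, his-59 was 3.41-fold higher and his-70 4.31-fold lower.

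Cuticle collagen genes went both ways: of 168, 97 fell (99 adjusted over the list alone), 55 rose and 16 did not pass, with 56 more than 2-fold lower and 15 more than 2-fold higher (median -0.50, mean -1.29, camera adjusted p = 1.4e-07, adjusted p = 0.16 with an estimated correlation). col-158 fell 408-fold, col-40 97.9-fold and col-37 66.9-fold. In the list of moulting and epidermis genes, 29 of 47 rose (30 adjusted over the list alone) and 12 fell. Its median was 0.27 and its mean -0.04, and camera did not call it (adjusted p = 0.0859): the hedgehog-related gene wrt-1 rose 2.06-fold and the cuticlin gene cut-6 fell 11.9-fold. Of 25 pharyngeal muscle genes, 20 fell and 3 rose (median -0.55, camera adjusted p = 2.9e-06, adjusted p = 0.115 with an estimated correlation). The pharyngeal myosin gene myo-2 fell from 290.0 ± 8.38 to 151 ± 2.41 CPM and abu-7 5.90-fold, whereas phat-4, expressed in pharyngeal gland cells, rose 5.14-fold. Body wall muscle genes were higher in 30 of 45 cases and lower in 7, without a call (median 0.19, camera adjusted p = 0.0556). Of these, the integrin gene pat-3 was 1.49-fold higher and the troponin I gene tni-3 2.00-fold lower. Extracellular matrix and basement membrane genes (20 of 33 higher, 5 lower, median 0.16, camera adjusted p = 0.153), which include epi-1 (1.36-fold higher) and nid-1 (1.48-fold lower), were not called. Neither were the genes of distal tip cell, gonad sheath and spermatheca (14 of 26 higher, 6 lower, median 0.14, camera adjusted p = 0.576), those of coelomocytes and excretory cell (13 of 22 higher, 14 adjusted over the list alone, 5 lower, median 0.15, camera adjusted p = 0.373), or those of uterus, vulva and egg-laying (10 of 22 higher, 5 lower, camera adjusted p = 0.809), whose median of 0.09 became -0.01 with relative log expression factors.

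In the nervous system lists, 72 neuropeptide genes rose, 12 of them by more than 2-fold, 11 fell and 21 did not pass (median 0.44, camera adjusted p = 0.0059, adjusted p = 0.565 with an estimated correlation). flp-18 went from 18.9 ± 0.717 to 42.9 ± 3.14 CPM and nlp-12 from 8.93 ± 0.776 to 20.3 ± 0.28 CPM, while nlp-24 fell 1.80-fold. Of 15 touch receptor neuron genes, 12 rose and none fell (median 0.47, camera adjusted p = 0.012, adjusted p = 0.123 with an estimated correlation), among them the tubulin gene mec-7, 1.54-fold, and mec-5, 1.87-fold. Of 59 netrin and axon guidance genes, 40 rose and 8 fell, none by more than 2-fold (median 0.24, camera adjusted p = 0.0344, adjusted p = 0.549 with an estimated correlation). unc-71 rose 1.66-fold and the Eph receptor gene vab-1 1.46-fold, and the homeobox gene zag-1 fell 1.80-fold. The call of this list ended with relative log expression factors (adjusted p = 0.123), with library sizes alone (0.0743) and without WT replicate 1 (0.0539). The remaining nervous system lists were not called. Synaptic vesicle and transmitter genes were higher in 25 of 50 cases, 24 adjusted over the list alone, and lower in 6 (camera adjusted p = 0.576), and their median of 0.10 became -0.01 with relative log expression factors. Neurotransmitter receptor and ion channel genes were higher in 24 of 55 cases, 23 adjusted over the list alone, and lower in 10 (camera adjusted p = 0.9, direction down), and their median of 0.06 became -0.04 with relative log expression factors. Ciliated sensory neuron genes were higher in 8 of 53 cases and lower in 14, 11 adjusted over the list alone (median -0.03, camera adjusted p = 0.226). Of these, the channel gene tax-2 was 3.16-fold lower. Of 17 glia genes, 8 were higher and 3 lower (median 0.30, camera adjusted p = 0.739). Of these, the channel gene delm-2 was 10.1-fold higher and vap-1 2.22-fold lower.

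Intestine genes fell in 14 of 27 cases and rose in 8 (median -0.15, camera adjusted p = 0.0117, adjusted p = 0.232 with an estimated correlation). The metallothionein gene mtl-2 fell 40.7-fold to 0.165 ± 0.0613 CPM, the peptide transporter gene pept-1 fell 1.81-fold, and the ferritin gene ftn-1 rose 2.96-fold. Lipid metabolism genes fell in 30 of 60 cases and rose in 19 (median -0.14, camera adjusted p = 0.00148, adjusted p = 0.217 with an estimated correlation): the acyl-CoA synthetase gene acs-2 fell 8.23-fold, the desaturase gene fat-5 fell 13.4-fold and the elongase gene elo-4 7.53-fold. Genes of the intracellular pathogen response fell in 25 of 40 cases, 21 of them by more than 2-fold, and rose in 9 (median -1.07, camera adjusted p = 5.4e-05, adjusted p = 0.115 with an estimated correlation). Of these, pals-26 was 7.71-fold and pals-14 6.12-fold lower. Innate immune effectors split, with 126 of 272 higher (127 adjusted over the list alone) and 114 lower, 61 and 67 of them beyond 2-fold. Their median of 0.09 became -0.01 with relative log expression factors, their mean was -0.29, and camera, pointing down, did not call them (adjusted p = 0.562): dod-24 rose 4.34-fold and dod-22 3.77-fold. Heat shock and unfolded protein response genes (14 of 30 higher, 10 lower, camera adjusted p = 0.809, direction down) had a median of 0.02 that became -0.08 with relative log expression factors and -0.03 with library sizes alone, with hsp-43 2.15-fold higher and hsp-70 3.61-fold lower. Xenobiotic and oxidative defence genes (98 of 198 higher, 63 lower, median 0.15, camera adjusted p = 0.809, direction down) were not called, and among them cyp-14A5 rose 3.41-fold and cyp-35A2 fell 4.63-fold. Energy metabolism and insulin signalling genes (20 of 52 higher, 18 lower, camera adjusted p = 0.361, direction down) had a median of 0.02 that became -0.08 with relative log expression factors and -0.03 with library sizes alone, and the glyoxylate cycle gene icl-1 fell 3.08-fold. Mitochondrially encoded genes rose in 10 of 12 cases, 5 by more than 2-fold, and fell in 1 (median 0.80, camera adjusted p = 0.0059, adjusted p = 0.292 with an estimated correlation). Of these, WBGene00010965 was 2.54-fold higher and WBGene00010961 2.49-fold lower. Cytosolic ribosome genes were higher in 49 of 82 cases, 48 adjusted over the list alone, and lower in 5, without a call (median 0.14, camera adjusted p = 0.0535). Of these, rps-16 was 1.36-fold higher and rps-23 1.61-fold lower.

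The count of changed genes depended on the low-count filter: with at least 5 CPM in at least 3 libraries, which left 11491 genes, 1615 were called. Scaling shifted the median of all genes, which was 0.16 for UNC5 against WT, -0.11 for PATR1 against WT and -0.04 for PATR1 against UNC5 with TMM factors, 0.06, -0.16 and 0.00 with relative log expression factors, and 0.11, -0.23 and -0.11 with library sizes alone, and list medians are to be set against these values.

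**Figure D2:**
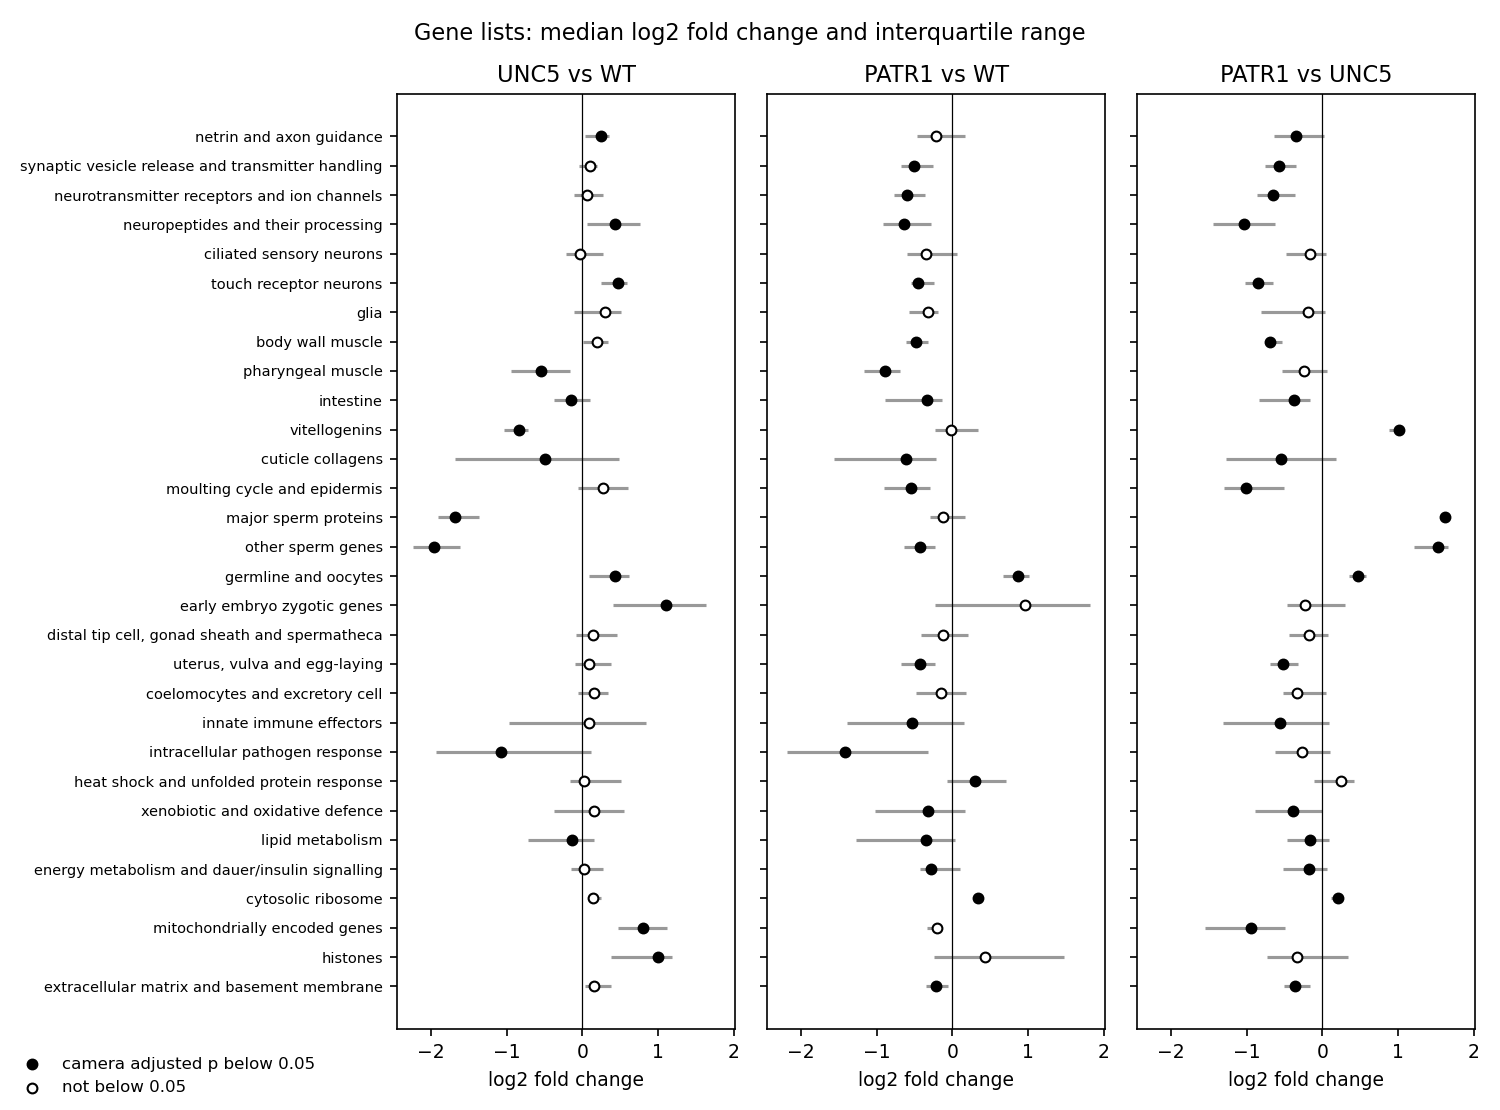
Median log2 fold change (points) and interquartile range (bars) of the tested genes of each of the 30 lists in the 3 comparisons; filled points are lists with a camera adjusted p below 0.05 at the preset correlation, open points are lists without. Sperm lists lie lowest in UNC5 against WT (medians -1.68 and -1.95) and highest in PATR1 against UNC5 (1.62 and 1.53), and in UNC5 against WT the medians of synaptic vesicle, neurotransmitter receptor, uterus, innate immune, heat shock and energy metabolism genes, all between 0.02 and 0.10, turn negative with relative log expression factors.

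In PATR1, germline and oocyte genes were called higher than in WT, and neuropeptide, neurotransmitter receptor, synaptic, touch neuron, muscle, collagen, moulting and intestine genes were called lower. None of these list calls held with an estimated correlation (adjusted p = 0.0934 for germline and oocytes), and netrin and axon guidance genes and ciliated sensory neuron genes were not called. All 69 germline and oocyte genes tested were higher, 20 of them by more than 2-fold, and the oocyte gene oma-2 went from 133 ± 2.20 to 307 ± 7.10 CPM (log2 fold change 1.21 ± 0.031, adjusted p = 9.5e-26). Within the same limits the largest rise was in delm-2, a sodium channel subunit gene expressed in glia, from 0.187 ± 0.0305 to 13.3 ± 0.597 CPM (71.2-fold, log2 fold change 6.14 ± 0.12, adjusted p = 8.2e-29). Of the genes within these limits collagen genes fell furthest: col-114, at 107 ± 0.0884 CPM in WT, had 0 counts in all 3 PATR1 libraries, which makes it at least 4837-fold lower. In total 2885 genes passed, 1054 higher and 1831 lower, and the groups did not overlap for 84.0% of genes against 10% by chance. On the adjusted p alone 14640 of 17512 passed, 6780 higher and 7860 lower, against which list counts are to be set.

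Other large rises in PATR1 were clec-190 (10.9-fold), tbb-6 (9.70-fold), the ribonuclease H gene rnh-1.3 (8.49-fold), pho-10 (7.25-fold), the glutathione transferase gene gst-38 (5.47-fold), the transporter gene pgp-8 (5.31-fold) and the zinc transporter gene zipt-2.3 (5.23-fold). Among the falls, col-185 and col-35 also had 0 counts in PATR1 and were at least 3380-fold and 3348-fold lower than in WT. col-37 had 1 count in PATR1, a ratio of 49479 with a counting interval of 8880 to 1954400, and col-164 had 2 counts, a ratio of 11314 with an interval of 3132 to 93424. col-102 was 11248-fold lower, col-84 8526-fold, and col-36 fell from 974 ± 25.3 to 0.167 ± 0.0669 CPM, or 6019-fold. Without PATR1 replicate 1 the log2 fold change moved from -13.36 to -14.06 in col-102 and from -12.23 to -12.90 in cut-1. Without that library it moved from -12.998 to -13.80 in col-84. Without PATR1 replicate 3 that of col-102 was -12.68, and without replicate 2 that of col-37 moved from -15.17 to -17.17. With the unstranded counts, which include reads of the opposite strand, the log2 fold change was smaller, -6.66 in col-35, -10.12 in col-84, -11.41 in col-164, -12.36 in col-114, -12.51 in col-102 and -9.49 in col-123. Floors are 3 counts over the group, and floors and intervals cover counting error only. Setting genes at or below the floor to their bound moved a list median by at most 0.02, in the 8 results that held such genes.

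For PATR1 against WT, camera called 20 of the 30 lists, 3 higher and 17 lower, and none of the calls held with an estimated correlation. The PATR1 libraries also held 2.86% to 6.02% of reads without a place in the genome, against at most 0.629% in WT, and 3.13% to 3.16% of reads with several places.

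The rise of the germline and oocyte genes had a median of 0.87 (camera adjusted p = 5.8e-22, adjusted p = 0.0934 with an estimated correlation). Of these, nos-2 was 2.75-fold, pos-1 2.45-fold and chs-1 2.27-fold higher. Early embryo zygotic genes rose in 20 of 33 cases, 16 by more than 2-fold, and fell in 8, without a call (median 0.96, camera adjusted p = 0.0571). Of these, vet-6 rose 5.81-fold and pal-1 1.95-fold. Of 41 other sperm genes, 31 fell and 1, spe-39, rose 1.53-fold (median -0.42, camera adjusted p = 1.1e-04, adjusted p = 0.0934 with an estimated correlation). spe-4, a presenilin gene, fell 1.97-fold and gsp-4 1.74-fold. Major sperm protein genes split, with 11 of 29 higher and 14 lower (median -0.13, camera adjusted p = 0.69): msp-55 rose 1.52-fold and msp-56 fell 1.53-fold. The vitellogenin genes split as well, 3 higher and 3 lower (median -0.02, camera adjusted p = 0.924), with vit-2 higher (log2 fold change 0.59 ± 0.044) and vit-1 2.19-fold lower. Of 32 histone genes, 17 rose, 12 by more than 2-fold, and 8 fell, without a call (median 0.43, camera adjusted p = 0.143), his-59 being 3.53-fold higher. Cytosolic ribosome genes rose in 80 of 82 cases and fell in 2, none by more than 2-fold (median 0.34, camera adjusted p = 4.6e-10, adjusted p = 0.281 with an estimated correlation). Of these, rpl-11.1 went from 645 ± 24.6 to 1093 ± 38.6 CPM.

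Of the neuropeptide genes 81 fell, 22 by more than 2-fold, 9 rose and 14 did not pass (median -0.64, camera adjusted p = 2.0e-06, adjusted p = 0.221 with an estimated correlation). flp-33 fell 4.84-fold and nlp-24 2.57-fold, and egl-3, which encodes a neuropeptide-processing protease, went from 223 ± 5.01 to 147 ± 5.34 CPM. Of 55 neurotransmitter receptor and ion channel genes, 46 fell and 3 rose (median -0.60, camera adjusted p = 1.1e-05, adjusted p = 0.132 with an estimated correlation), among them the GABA receptor genes gbb-2 (2.03-fold) and unc-49 (1.74-fold) and the potassium channel gene slo-1 (1.82-fold). Synaptic vesicle and transmitter genes fell in 40 of 50 cases and rose in 8 (median -0.51, camera adjusted p = 3.0e-04, adjusted p = 0.234 with an estimated correlation). The complexin gene cpx-1 fell 2.33-fold and unc-25, which encodes the enzyme that makes GABA, 2.08-fold, while the tyrosine decarboxylase gene tdc-1 rose 2.06-fold. Of 15 touch receptor neuron genes, 12 fell and 1, mec-15, rose 1.81-fold (median -0.46, camera adjusted p = 0.0318, adjusted p = 0.132 with an estimated correlation). The tubulin gene mec-12 fell 1.55-fold. Netrin and axon guidance genes (17 of 59 higher, 32 lower, median -0.21, camera adjusted p = 0.172) were not called: zag-1 fell 3.67-fold and unc-71 rose 2.15-fold. Nor were ciliated sensory neuron genes, of which 7 of 53 rose and 31 fell, 30 adjusted over the list alone (median -0.35, camera adjusted p = 0.0955). Of these, tax-2 was 4.52-fold lower. Glia genes fell in 13 of 17 cases and rose in 3, without a call (median -0.33, mean 0.03, camera adjusted p = 0.155, direction down). Of these, ptr-10 fell 2.42-fold.

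Body wall muscle genes fell in 39 of 45 cases and rose in 4, none by more than 2-fold (median -0.48, camera adjusted p = 2.2e-07, adjusted p = 0.122 with an estimated correlation), with the twitchin gene unc-22 going from 490 ± 2.35 to 304 ± 9.82 CPM and the troponin T gene tnt-3 1.94-fold lower. Pharyngeal muscle genes fell in 22 of 25 cases and rose in 3 (median -0.88, camera adjusted p = 1.4e-05, adjusted p = 0.122 with an estimated correlation), the pharyngeal myosin gene myo-1 by 2.53-fold and myo-2 also (log2 fold change -1.20 ± 0.032), while phat-4 rose 5.06-fold. Of 168 cuticle collagen genes, 142 fell, 64 by more than 2-fold, and 16 rose, 17 adjusted over the list alone (median -0.61, mean -2.01, camera adjusted p = 7.7e-14, adjusted p = 0.122 with an estimated correlation). Of these, col-2 was 3060-fold and col-158 383-fold lower. Moulting and epidermis genes fell in 41 of 47 cases and rose in 3 (median -0.54, camera adjusted p = 2.6e-08, adjusted p = 0.122 with an estimated correlation). Of these, cut-6 was 23.8-fold and the fibrillin-like gene fbn-1 2.83-fold lower. Intestine genes fell in 21 of 27 cases and rose in 3 (median -0.34, camera adjusted p = 2.5e-04, adjusted p = 0.122 with an estimated correlation): the cathepsin B-like protease genes cpr-1 and cpr-4 fell 5.66-fold and 4.48-fold, and pept-1 2.67-fold. Uterus, vulva and egg-laying genes fell in 15 of 22 cases and rose in 2 (median -0.43, camera adjusted p = 0.0156, adjusted p = 0.162 with an estimated correlation). Of these, ida-1 was 1.75-fold lower. Extracellular matrix and basement membrane genes fell in 22 of 33 cases and rose in 4 (median -0.21, camera adjusted p = 0.0151, adjusted p = 0.367 with an estimated correlation). Of these, the fibulin gene fbl-1 fell 1.74-fold. No call was made for distal tip cell, gonad sheath and spermatheca genes (8 of 26 higher, 12 lower, median -0.12, camera adjusted p = 0.606), where the Delta-like ligand gene apx-1 rose 2.09-fold, nor for coelomocyte and excretory cell genes (9 of 22 higher, 12 lower, median -0.15, camera adjusted p = 0.586), where cup-5 rose 1.75-fold and exc-5 fell 1.68-fold.

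Innate immune effectors fell in 164 of 272 cases, 93 by more than 2-fold, and rose in 65 (median -0.53, camera adjusted p = 5.2e-04, adjusted p = 0.122 with an estimated correlation): clec-61 fell 22.2-fold and clec-60 went from 471 ± 13.8 to 62.6 ± 2.27 CPM. Intracellular pathogen response genes fell in 31 of 40 cases and rose in 5 (median -1.42, camera adjusted p = 3.1e-04, adjusted p = 0.122 with an estimated correlation). Of these, pals-26 fell 7.27-fold. Lipid metabolism genes fell in 41 of 60 cases and rose in 14 (median -0.35, camera adjusted p = 2.5e-04, adjusted p = 0.132 with an estimated correlation), with acdh-1, an acyl-CoA dehydrogenase gene, 73.4-fold lower and acs-2 also lower (log2 fold change -5.83 ± 0.051). Energy metabolism and insulin signalling genes fell in 32 of 52 cases and rose in 15 (median -0.27, camera adjusted p = 0.0231, adjusted p = 0.32 with an estimated correlation): icl-1 fell 6.47-fold. Xenobiotic and oxidative defence genes fell in 107 of 198 cases and rose in 50 (median -0.31, camera adjusted p = 0.0259, adjusted p = 0.183 with an estimated correlation). Of these, ugt-65 was 5.52-fold lower and cyp-14A5 3.85-fold higher. Heat shock and unfolded protein response genes rose in 19 of 30 cases and fell in 8 (median 0.30, camera adjusted p = 0.0259, adjusted p = 0.132 with an estimated correlation), hsp-16.41 by 3.20-fold and the heat shock factor gene hsf-1 by 1.68-fold, but the call ended with library sizes alone (adjusted p = 0.0546). Of 12 mitochondrially encoded genes, 1 was higher and 8 lower, without a call (median -0.20, camera adjusted p = 0.0774). Of these, WBGene00010961 fell 1.92-fold.

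Of the calls for PATR1 against WT, 36.5% were higher, but 24.9% with library sizes alone. The stricter low-count filter left 1387 calls, and 3082 were made without PATR1 replicate 1, the library with the largest unmapped share.

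Compared directly, sperm, germline and yolk protein genes were called higher in PATR1 than in UNC5, and body wall muscle, moulting, innate immune and neuropeptide genes were called lower. The calls for yolk protein and neuropeptide genes did not hold with an estimated correlation (adjusted p = 0.131 and 0.103), and pharyngeal muscle and intracellular pathogen response genes were not called. Within the same limits the largest rises were in clec-230, a C-type lectin gene, from 2.08 ± 0.185 CPM in UNC5 to 22.3 ± 0.642 CPM in PATR1 (10.7-fold, log2 fold change 3.42 ± 0.081, adjusted p = 1.1e-26) and rnh-1.3, from 6.59 ± 0.341 to 59.8 ± 1.17 CPM (9.07-fold). acdh-1 fell from 62.8 ± 3.08 to 0.286 ± 0.0689 CPM (224-fold, log2 fold change -7.80 ± 0.096, adjusted p = 3.6e-34), and scl-12, which encodes a secreted SCP-like protein, from 32.2 ± 1.39 CPM to 0 counts, at least 1464-fold. In total 3666 genes passed, 1656 higher and 2010 lower in PATR1, and the groups did not overlap for 79.5% of genes against 10% by chance. On the adjusted p alone 13774 of 17512 passed, 6614 higher and 7160 lower, against which list counts are to be set. The aspartyl protease gene asp-17 (8.32-fold), delm-2 (7.02-fold) and col-88 (6.08-fold) followed among the rises. scl-11 had 2 counts in PATR1, a ratio of 1700.5 with a counting interval of 470.4 to 14048, col-37 had 1 count, a ratio of 740 with an interval of 132 to 29267, and col-185 had none, at least 41.5-fold lower. The fitted log2 fold change of scl-11 moved from -10.50 to -13.29 without PATR1 replicate 1 and to -9.87 without replicate 3, and that of col-37 from -9.10 to -11.10 without replicate 2.

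In this comparison camera called 21 of 30 lists, 5 higher and 16 lower, and 7 calls held with an estimated correlation: major sperm proteins, other sperm genes, germline and oocytes, body wall muscle, moulting and epidermis, touch receptor neurons and innate immune effectors. Of 29 major sperm protein genes, 28 were higher in PATR1, all by more than 2-fold, and 1 did not pass (median 1.62, camera adjusted p = 9.9e-15, adjusted p = 0.043 with an estimated correlation). Of these, msp-76 was 3.28-fold higher. Of 41 other sperm genes, 38 were higher and 2 lower (median 1.53, camera adjusted p = 2.4e-12, adjusted p = 0.00985 with an estimated correlation). Of these, ssq-2 was higher by 3.73-fold and gsp-3 by 3.45-fold. Germline and oocyte genes were higher in 66 of 69 cases and lower in none (median 0.47, camera adjusted p = 8.4e-18, adjusted p = 0.043 with an estimated correlation), with glh-1, which encodes a helicase of germ granules, 2.05-fold higher. All 6 vitellogenin genes were higher, 3 by more than 2-fold (median 1.01, camera adjusted p = 1.3e-05, adjusted p = 0.131 with an estimated correlation). Of these, vit-2 went from 12490 ± 320 to 29600 ± 1120 CPM. Cytosolic ribosome genes were higher in 61 of 82 cases and lower in 2 (median 0.21, camera adjusted p = 1.9e-06, adjusted p = 0.345 with an estimated correlation). Of these, rpl-11.1 was higher by 1.93-fold. Early embryo zygotic genes (8 of 33 higher, 14 lower, median -0.23, camera adjusted p = 0.559), among them hlh-1 (1.92-fold lower), and histone genes (8 of 32 higher, 13 lower, median -0.33, camera adjusted p = 0.381), among them his-24 (1.95-fold lower) and his-70 (2.90-fold higher), were not called.

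Of the neuropeptide genes 92 were lower in PATR1 than in UNC5, 54 by more than 2-fold, 6 were higher and 6 did not pass (median -1.03, camera adjusted p = 1.3e-13, adjusted p = 0.103 with an estimated correlation). Of these, nlp-50 was 5.62-fold, nlp-21 3.41-fold and flp-18 3.26-fold lower. Touch receptor neuron genes were lower in 14 of 15 cases and higher in 1 (median -0.84, camera adjusted p = 1.2e-04, adjusted p = 0.043 with an estimated correlation), mec-17, which encodes a tubulin acetyltransferase, by 2.22-fold. Synaptic vesicle and transmitter genes were lower in 41 of 50 cases and higher in 6 (median -0.58, camera adjusted p = 2.1e-06, adjusted p = 0.143 with an estimated correlation). Of these, unc-25 was lower by 2.35-fold. Neurotransmitter receptor and ion channel genes were lower in 47 of 55 cases, 48 adjusted over the list alone, and higher in 1 (median -0.65, camera adjusted p = 2.1e-07, adjusted p = 0.0975 with an estimated correlation). Of these, the gap junction gene unc-9 was lower by 2.04-fold. Netrin and axon guidance genes were lower in 40 of 59 cases and higher in 11 (median -0.34, camera adjusted p = 2.5e-04, adjusted p = 0.17 with an estimated correlation). Of these, madd-4 was lower by 2.64-fold and the Slit gene slt-1 by 2.35-fold. Ciliated sensory neuron genes (3 of 53 higher and 19 lower, or 2 and 17 adjusted over the list alone, median -0.17, camera adjusted p = 0.156) and glia genes (3 of 17 higher, 11 lower, median -0.19, camera adjusted p = 0.15) were not called, with che-14 2.58-fold and ptr-10 3.04-fold lower.

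Body wall muscle genes were lower in 42 of 45 cases and higher in 3, none by more than 2-fold (median -0.69, camera adjusted p = 2.7e-13, adjusted p = 0.043 with an estimated correlation), with unc-89 going from 544 ± 8.87 to 309 ± 15.5 CPM and the titin-like gene ttn-1 1.78-fold lower. Moulting and epidermis genes were lower in 42 of 47 cases, 25 by more than 2-fold, and higher in 3 (median -1.01, camera adjusted p = 4.8e-13, adjusted p = 0.043 with an estimated correlation). Of these, fbn-1 was lower by 3.92-fold and mlt-10 by 3.11-fold. Of 168 cuticle collagen genes, 49 were higher, 16 did not pass and the rest were lower, 105 of them lower adjusted over the list alone (median -0.55, camera adjusted p = 5.9e-04, adjusted p = 0.209 with an estimated correlation), col-176 18.5-fold lower and col-120 5.94-fold higher. Intestine genes were lower in 21 of 27 cases and higher in 4 (median -0.37, camera adjusted p = 1.9e-04, adjusted p = 0.1 with an estimated correlation). Of these, cpr-1 was lower by 4.60-fold. Extracellular matrix and basement membrane genes were lower in 27 of 33 cases and higher in 1 (median -0.36, camera adjusted p = 5.3e-06, adjusted p = 0.143 with an estimated correlation). Of these, the netrin gene unc-6 was lower by 2.09-fold. Uterus, vulva and egg-laying genes were lower in 16 of 22 cases and higher in 1 (median -0.51, camera adjusted p = 0.00122, adjusted p = 0.103 with an estimated correlation). Of these, sem-2 was lower by 1.89-fold. Pharyngeal muscle genes (4 of 25 higher, 14 lower, median -0.24, camera adjusted p = 0.0737), distal tip cell, gonad sheath and spermatheca genes (4 of 26 higher, 15 lower, median -0.17, camera adjusted p = 0.0771) and coelomocyte and excretory cell genes (4 of 22 higher, 13 lower, median -0.33, camera adjusted p = 0.0509) were not called, and myo-1, gon-1 and inx-13 were 1.32-fold, 1.56-fold and 1.56-fold lower.

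Innate immune effectors were lower in PATR1 than in UNC5 in 172 of 272 cases and higher in 57, 58 adjusted over the list alone (median -0.56, camera adjusted p = 5.1e-06, adjusted p = 0.043 with an estimated correlation). Of these, clec-61 was lower by 9.71-fold and clec-70 by 8.46-fold. Mitochondrially encoded genes were lower in 10 of 12 cases and higher in 1 (median -0.93, camera adjusted p = 6.2e-05, adjusted p = 0.131 with an estimated correlation). Of these, WBGene00010965 was lower by 3.13-fold. Xenobiotic and oxidative defence genes were lower in 118 of 198 cases, 117 adjusted over the list alone, and higher in 26 (median -0.38, camera adjusted p = 2.8e-04, adjusted p = 0.085 with an estimated correlation), ugt-65 by 4.34-fold, while gst-24 was 5.37-fold higher. Lipid metabolism genes were lower in 34 of 60 cases, 35 adjusted over the list alone, and higher in 15, 16 adjusted over the list alone (median -0.16, camera adjusted p = 0.0113, adjusted p = 0.242 with an estimated correlation). Of these, acs-2 was lower by 6.92-fold. Energy metabolism and insulin signalling genes were lower in 32 of 52 cases and higher in 13 (median -0.18, camera adjusted p = 0.0113, adjusted p = 0.242 with an estimated correlation), pck-1, which encodes a gluconeogenic enzyme, by 2.49-fold. Heat shock and unfolded protein response genes (15 of 30 higher, 9 lower, median 0.25, camera adjusted p = 0.0602) and intracellular pathogen response genes (7 of 40 higher, 20 lower, median -0.27, camera adjusted p = 0.364) were not called, with hsp-16.41 3.72-fold higher, hsp-12.6 13.8-fold lower and pals-32 2.37-fold lower. The stricter low-count filter left 1842 calls between the mutant groups.

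**Figure D3:**
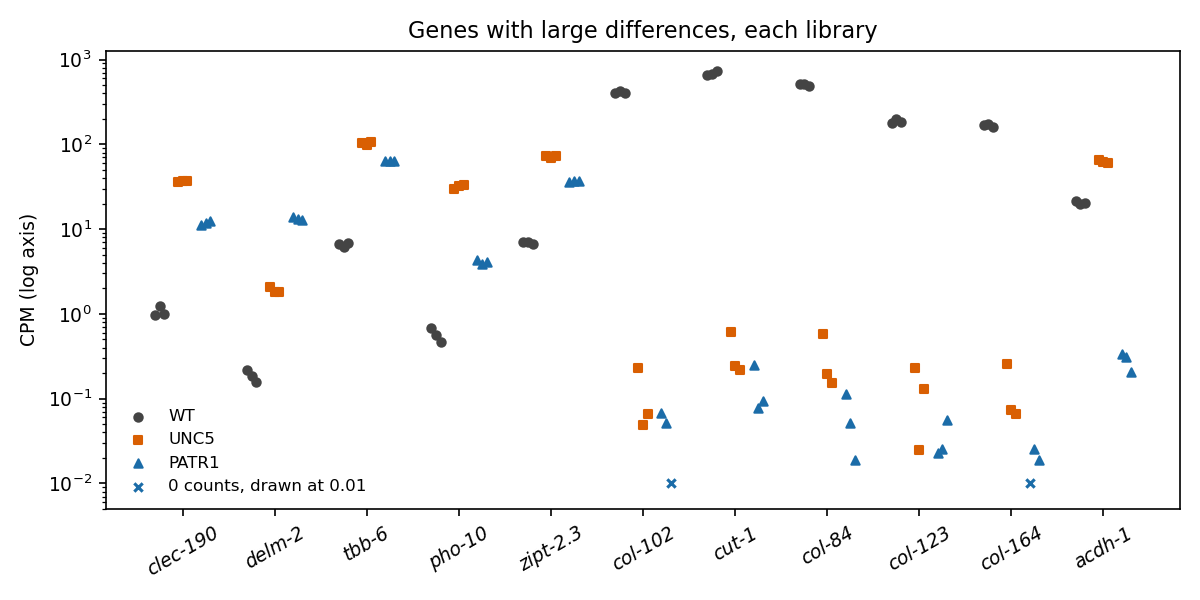
CPM on a log axis in each of the 9 libraries (points, 3 per genotype) of the 10 genes named for their change in both mutant groups, and of acdh-1; crosses at 0.01 mark libraries with 0 counts. clec-190, delm-2, tbb-6, pho-10 and zipt-2.3 lie above WT in both mutant groups, the collagen genes and the cuticlin gene cut-1 lie far below WT in both, and acdh-1 is highest in UNC5 (62.8 CPM) and lowest in PATR1 (0.286 CPM).

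Both mutant groups shared part of their difference from WT. 539 genes were called higher in both and 746 lower in both, where independent calls of these numbers would give 74.7 and 251. Within the same limits on CPM and symbol, the genes with the largest smaller change in both were clec-190, delm-2, tbb-6, pho-10 and zipt-2.3 (10.3-fold higher in UNC5 and 5.23-fold in PATR1) among the rises and col-102, cut-1, col-84, col-123 and col-164 among the falls. Another 127 genes were called in opposite directions, 113 of them higher in UNC5 and lower in PATR1 and 14 the reverse, where independent calls would give 129.8 and 145. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.67, a Spearman rho of 0.58 and a covariance of 0.917. Because the comparisons share the 3 WT libraries, 20 simulations drew all 9 libraries from the WT means, with the simulated WT libraries shared by both comparisons. They gave a mean r of 0.41, a mean covariance of 0.0109 and no shared calls. At most 1 gene was called in any simulated comparison, so the absence of shared calls there is no measure for the real ones. The simulations hold only the fitted spread between libraries, not a departure common to the 3 real WT libraries. The observed covariance less the simulated one was 0.906. As 3 WT libraries cannot be divided between the comparisons, part of that excess may come from the shared WT libraries. With the stricter low-count filter 150 genes were called higher in both and 380 lower in both.

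Calls were unevenly spread over the chromosomes (Fisher's exact test, two-sided, adjusted over 6 chromosomes). On the X chromosome 10.3% of tested genes were called in UNC5 against 22.5% elsewhere (odds ratio 0.396, adjusted p = 2.1e-48), and 14.6% in PATR1 against 16.8% elsewhere (odds ratio 0.851, adjusted p = 0.00995). Chromosome III was also low, with odds ratios of 0.662 in UNC5 (adjusted p = 5.4e-13) and 0.529 in PATR1 (adjusted p = 3.5e-22), and chromosome V was high, with 1.35 (adjusted p = 1.6e-11) and 1.74 (adjusted p = 2.2e-31). Chromosome II was high in both, with 1.27 (adjusted p = 1.0e-06) and 1.18 (adjusted p = 0.00294). Chromosome IV, which carries unc-5, was high in UNC5 (26.1% against 19.7%, odds ratio 1.43, adjusted p = 1.1e-13) and not in PATR1 (odds ratio 0.976, adjusted p = 0.663), and chromosome I was low in PATR1 (odds ratio 0.745, adjusted p = 1.3e-06) and gave 0.943 in UNC5 (adjusted p = 0.271). Between the mutant groups, IV and V were high (1.34 and 1.41, adjusted p = 1.3e-09 and 8.4e-15) and III and X low (0.648 and 0.568, adjusted p = 2.9e-14 and 3.4e-21), and I and II gave 0.946 (adjusted p = 0.283) and 1.08 (adjusted p = 0.161). Within 2 Mb of unc-5, 31.2% of 730 tested genes were called in UNC5 against 24.4% on the rest of the chromosome (odds ratio 1.41, Fisher's exact p = 3.2e-04), with no such difference in PATR1 (odds ratio 0.984, p = 0.91), and 29.7% against 23.7% between the mutant groups (odds ratio 1.36, p = 0.0014). Fisher's test treats genes as independent, which neighbouring genes that change together are not, so these p-values may be too small. The window was not tested with the adjusted p alone, and linkage to unc-5 was not tested. Whether sperm genes, most of which fell in UNC5, give part of these chromosome differences was not tested either. With the adjusted p alone, X stayed low, with odds ratios of 0.584 in UNC5 (adjusted p = 1.2e-27), 0.698 in PATR1 (adjusted p = 5.0e-10) and 0.725 between the mutant groups (adjusted p = 1.8e-09). II stayed high against WT, with 1.12 in UNC5 (adjusted p = 0.0347) and 1.14 in PATR1 (adjusted p = 0.0263). The differences on I in PATR1, on III and V, and on IV rested on the 2-fold limit. I in PATR1 turned high (1.47, adjusted p = 5.0e-10), and IV no longer passed in UNC5 (1.097, adjusted p = 0.0588) or between the mutant groups (1.09, adjusted p = 0.146). III was high against WT (1.24 in UNC5, 1.19 in PATR1), and V was low in PATR1 (0.781, adjusted p = 6.1e-07) and did not pass in UNC5 (0.921, adjusted p = 0.0588). Between the mutant groups neither III nor V passed (adjusted p = 0.146 for each).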

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

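The test of vitamin B12 and the test of a related gene, both for acdh-1, were chosen before their results were seen.

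Reads without a place in the genome averaged 4.10% in PATR1, against 0.624% in WT and 0.783% in UNC5, and reads in no annotated gene averaged 1.22% in UNC5, against 0.623% in WT and 0.720% in PATR1. Both shares lie outside the gene counts that were compared, and both are above the level in WT. What these reads hold was not analysed here, and no biological explanation was tested.

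Some results moved in opposite directions in the mutant groups relative to WT, and the difference was tested directly between the groups. The median log2 fold change in PATR1 against UNC5 was -1.03 for neuropeptide genes and -0.84 for touch receptor neuron genes. With an estimated correlation the call for neuropeptide genes was lost between the mutant groups (adjusted p = 0.103) and in both comparisons with WT (0.565 in UNC5, 0.221 in PATR1), and that for touch receptor neuron genes in both comparisons with WT (0.123 and 0.132), but not between the mutant groups (0.043). Among single genes, the log2 fold change in PATR1 against UNC5 was -7.80 for acdh-1, -3.76 for hsp-12.6, -2.49 for nlp-50, -10.50 for scl-11 and -13.64 for scl-12. All of these were higher in UNC5 and lower in PATR1 than in WT. For clec-230, which was lower in UNC5 and higher in PATR1, it was 3.42. The values for scl-11 and scl-12 are fitted ones that rest on 2 counts and 0 counts in PATR1 and depend on the prior count.

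acdh-1 encodes the first enzyme of a propionate breakdown pathway whose genes rise when vitamin B12 is scarce. Reads credited to its closest relative acdh-2 instead are argued against, since acdh-2 changed by -0.50 CPM in PATR1 relative to UNC5 while acdh-1 lost 62.5 CPM. Reads with several places in the genome are counted for no gene, so a loss of acdh-1 reads among them was not tested. A difference in vitamin B12 from the bacterial food may contribute and stays open. The 5 other genes tested as linked to the pathway had a median log2 fold change of -0.44. Of these 5, 2 were called lower, hphd-1 (-1.18) and nhr-68 (-1.35), which encodes a nuclear hormone receptor and not an enzyme of the pathway. A difference between the genotypes stays open too, as untested.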

How the results depend on the processing

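No alternative here was added after the data were examined. Of 280 counts and percentages under alternatives, 263 stayed within a factor of 1.5 (counts) or 10 percentage points (the share of calls that were higher), and 17 moved. Of 5521 fold changes of named genes, 5519 kept their direction and their side of the threshold; the 2 that lost significance were of WBGene00010964 in PATR1 against WT. Of 1080 list tests, 973 kept both, 52 lost a call, 51 gained one and 4 reversed. Of 36 chromosome odds ratios, 24 kept both. Calls shared with the reported ones made up 39.9% to 99.9%, lowest with the stricter filter.

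With the filter at 5 CPM in 3 libraries, which tests fewer genes, 1615 genes were called in UNC5 against WT (436 higher, 1179 lower), 1387 in PATR1 against WT (330 higher, 1057 lower, 23.8% higher) and 1842 in PATR1 against UNC5 (810 higher, 1032 lower). In both mutant groups 150 were then higher and 380 lower. With library sizes alone 24.9% of the PATR1 calls against WT were higher, and the cause was not tested.

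With an estimated correlation, camera called 1 list in UNC5 against WT, 0 lists in PATR1 against WT and 7 lists in PATR1 against UNC5. fry, which asks another question, called 28 lists in UNC5 against WT, and reversed to higher the neurotransmitter receptors and ion channels (adjusted p = 0.00598), innate immune effectors (1.2e-05), heat shock and unfolded protein response (5.8e-05) and xenobiotic and oxidative defence (3.6e-05).

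With the adjusted p alone, the odds ratios in UNC5 against WT were 1.28 on chromosome I and 1.24 on III, both reversed and significant, and 0.921 on V, on the other side of 1, and 1.097 on IV, neither significant. In PATR1 against WT they reversed to 1.47 on I, 1.19 on III and 0.781 on V, all significant. In PATR1 against UNC5 the ratio reversed to 1.29 on I, which was significant. III (1.09) and V (0.934) moved to the other side of 1 and IV was 1.09, none of them significant. With DESeq2, chromosome II became significant in PATR1 against UNC5 (1.13). The cause was not tested.

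With the replicate number as a replicate block, 3646, 2880 and 3664 genes were called in the 3 comparisons. The numbers do not pair the libraries: correlations of residuals between libraries of the same number were -0.049 to 0.046, and 2 of 9 libraries matched their own number best. Without 1 library, calls ran from 3739 to 3790 in UNC5 against WT, from 2966 to 3082 in PATR1 against WT and from 3702 to 3757 in PATR1 against UNC5. Depth limits the genes at or near 0 counts, whose folds are bounds or intervals.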

Other observations

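The tests of the cuticle genes and of the neuronal genes were chosen only after those results were seen, and the splits of the libraries before.

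Of 215 cuticle collagen, moulting and epidermis genes tested, 22 were more than 16-fold lower in both mutant groups than in WT, 21 of them collagen genes. Their summed level was 7902.5 CPM in WT, 46.01 CPM in UNC5 and 7.72 CPM in PATR1. Scaling shifts all genes alike, and over 3 scalings the median of all genes lay between 0.06 and 0.16 in UNC5 and between -0.23 and -0.11 in PATR1. That argues against scaling for these genes, which were picked for their falls and whose median log2 fold change nearest 0 was -8.12. Reads credited to related genes instead are argued against, since the other genes of both lists gained -44.1% of what these lost in UNC5, a loss rather than a gain. Reads with several places in the genome are counted for no gene. Their mean share was 4.84% in WT, 3.61% in UNC5 and 3.14% in PATR1, and thus not higher in the mutant groups. Larvae entering the dauer stage among the WT animals may explain the pattern and stay open. The 18 dauer-linked genes outside the cuticle had medians of -0.38 in UNC5 and -1.18 in PATR1, with members going both ways. A difference between the genotypes stays open as well, and one in culture or exact stage cannot be told apart from it.

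In PATR1 against WT, 277 neuronal genes had a median log2 fold change of -0.53, 232 other somatic genes -0.44 and the germline and oocyte genes 0.87. The median of the neuronal genes was -0.53 with TMM factors, -0.59 with relative log expression factors and -0.65 with library sizes alone. That of all genes was -0.11, -0.16 and -0.23, so the neuronal genes fell relative to it under each scaling. Because these scalings differ little, they cannot decide whether another scaling would bring the neuronal median to 0. Gene length is argued against by a neuronal median of -0.51 (interval -0.56 to -0.44) after its trend was removed. The medians of 11 lists of single somatic tissues ranged over 0.73, from -0.88 in pharyngeal muscle to -0.15 in coelomocytes and excretory cell (permutation p = 2.0e-04 over 10000 shufflings of genes between lists). The somatic lists thus did not fall alike, but the shufflings treat genes as independent. Whether list members are also expressed in the germline was not checked. The range therefore cannot decide whether a larger share of germline RNA is the whole cause. Such a share may be all or part of the cause, and a difference between the genotypes stays open, untested.

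The 10 splits of the 6 libraries of a comparison are too few to give a share under 0.05. The real split called 3645 genes in UNC5 against WT, 2885 in PATR1 against WT and 3666 in PATR1 against UNC5, and the highest other split called 0 in each, so 1 of 10 splits gave as many. For gene lists, the real splits called 15, 20 and 21 lists and the highest others 15, 20 and 22, with 2, 2 and 4 of 10 splits giving as many. The lowest others called 10, 15 and 17 lists. Every other split mixes both genotypes within its groups, which widens their spread and keeps part of the real difference. Neither the gene counts nor the list counts of these splits can therefore speak to chance. The 1285 genes called in both mutant groups in 1 direction were matched by 5 of 100 splits drawn from 840, the real one included, with a highest other of 2020, so chance cannot be excluded by this count. The 4 other splits that gave as many were among the 7 others with the 3 libraries of 1 genotype as their reference, and the highest with a mixed reference gave 0. A mixed reference widens the spread, and a reference of 1 genotype keeps a real difference between genotypes. These splits can therefore not speak to chance either.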
